A study of Homo sapiens with 12 samples.

How the data were processed

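The series measured cytoplasmic RNA of U2OS cells, a human osteosarcoma line, that carry K294A under doxycycline control. Per the labels' protocols, cells were induced with doxycycline at 1 ug/ml for 24 h, RNA was recovered from a cytoplasmic extract and passed through a ribosomal RNA removal kit, and part of the samples was then treated in vitro with Xrn1. Fragmented, biotin-labelled material was hybridised to 12 exon arrays. The labels give 4 groups of 3 arrays: induced untreated, induced Xrn1, uninduced untreated and uninduced Xrn1. The titles number the samples CM1 to CM6, with an X for Xrn1; samples 1 to 3 are induced and 4 to 6 uninduced, and replicates are named here by their order within a group. The title of CM1X carries replicate number 2, as does that of CM2X, and it was taken as replicate 1 because of its sample number. The labels call the samples biological replicates and do not state whether they come from separate cultures. Each p therefore rests on the spread between these samples, which the main fit pooled over all genes.

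The deposited values are log2 probe set values, 1 per probe set and array, made by the authors with RMA in the oligo package, per the submitters' processing notes; the software version and the array annotation are not given in the sources used here. The table holds 1411399 probe sets and values from -0.36 to 14.08. The medians of the 12 arrays lie between 2.09 and 2.25. Of the probe sets, 357604 carry exactly 1 gene symbol in the reference table, 15322 carry several and 1038473 carry none. The 19560 distinct symbols were matched to current ones: 16472 were current, 2966 were updated through an unambiguous synonym and 122 were kept as they stood. No column of values was left unmapped.

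A probe set was kept when its mean over the 12 arrays was above the median of that mean over all probe sets, 2.04. This left 258175 probe sets with 1 symbol. A gene's value on an array is the mean log2 value of its kept probe sets, and genes with at least 3 of them were tested, 16883 in all. The deposited values were not normalised again. Gene values were fitted with limma (lmFit and eBayes) over all 12 arrays and 4 group means, and 6 contrasts were tested: Xrn1 in uninduced cells, Xrn1 in induced cells, their average, induction without Xrn1, induction with Xrn1, and the difference of both Xrn1 effects (the interaction). P values were adjusted by Benjamini-Hochberg over the genes of each contrast, with a threshold of 0.05. With 8 residual degrees of freedom, limma estimated an infinite prior, so every gene received the common SD of 0.418; the standard error is therefore 0.34 for a simple contrast, 0.24 for the average and 0.48 for the interaction. The same contrasts were tested on 705699 single probe sets.

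In all, 23 gene lists were fixed before the data were examined, and 22 had at least 5 measured members. These were tested with camera at its preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a contrast, and each member was also counted after adjustment over its list alone. A correlation estimated for each list ranged from 0.183 to 0.656. Fry, which asks whether the members of a list move on balance in 1 direction and compares them with no other genes, was run beside it. Named genes follow a rule: for each contrast the 8 largest rises and the 8 largest falls among genes that passed and whose group values did not overlap, or as many as passed; up to 4 members of each list with the smallest p; and RNGTT, XRN1, RPLP0 and BOP1. Provisional names and antisense loci were left out. For the interaction, the ranges of the 9 Xrn1-minus-untreated differences had to be apart. Genes named outside this rule are marked as such.

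The fits were tested on simulated data with 200 of 16883 genes changed. With independent noise, a log2 change of 2 was recovered for 100% of changed genes in uninduced cells, 100% in induced cells, 100% in the average, 98% and 100% for induction without and with Xrn1, and 62% for the interaction. A log2 change of 1 was recovered for 31%, 21%, 75%, 34%, 32% and 3%. With the residual covariance of the real genes, these were 80%, 92%, 100%, 95%, 97% and 0% for a change of 2, and 11%, 5%, 91%, 2%, 3% and 0% for a change of 1.

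The alternatives fixed before the data were examined were the median of a gene's probe sets, no filter on dim probe sets, only probe sets with a mean above the upper quartile (2.76), 1 kept probe set per gene, centring of each array on its median gene, cyclic loess between arrays, a trended and robust prior, array weights, a fit of only the groups compared, the replicate number as a block, a fold of at least 1.5, and leaving out each array. Alternatives added after the data had been seen were each gene's own spread without a prior, leaving out CM5 and CM5X (uninduced untreated replicate 2 and uninduced Xrn1 replicate 2), genes with a mean above 5, and array weights computed gene by gene. A comparison of the 5' and 3' parts of genes, with its alternatives, was not run, because the positions of probe sets are not given in the sources used here. RMA normalises before it summarises, and raw intensities were not used here. R 4.3.3, limma 3.58.1, statmod 1.5.0 and data.table (1.17.8) were used. Arrays give no depth, and their number limits the precision.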

Results

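Levels of 16883 genes were measured in cytoplasmic RNA of U2OS osteosarcoma cells on 12 exon arrays, 3 in each of 4 groups. Cells carried K294A, an inactive form of the cytoplasmic capping enzyme, under doxycycline control, and RNA was or was not treated in vitro with Xrn1, an exonuclease that degrades RNA with a 5' monophosphate from its 5' end. The study asks which RNAs are re-capped in the cytoplasm. All levels and changes below are on the log2 scale, and 3 arrays per group limit the precision. The first principal component of the gene values held 56.1% of the variance and the second 27.0%.

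The 12 arrays differed in signal and in how well they matched their groups. Genes above a level of 6 numbered 327, 823 and 596 on the induced untreated arrays, 1114, 760 and 914 on the uninduced untreated arrays, and 110 to 298 on the Xrn1 arrays. Across genes, which are not independent replicates, correlations within a group were 0.835 to 0.888 for induced untreated, 0.942 to 0.959 for induced Xrn1, 0.837 to 0.967 for uninduced untreated and 0.711 to 0.918 for uninduced Xrn1. Induced untreated replicate 3 correlated at 0.979 and 0.952 with uninduced untreated replicates 3 and 1, and at 0.870 and 0.835 with induced untreated replicates 1 and 2. Induced untreated replicate 2 correlated at 0.894 with uninduced untreated replicate 1, and at 0.888 and 0.835 within its group. Over all probe sets, induced untreated replicate 1 correlated at 0.773 with uninduced Xrn1 replicate 2, and at 0.679 and 0.734 within its group. After centring of each array on its median gene, the medians of all genes moved from -0.27 to 0.09 for Xrn1 in uninduced cells, from 0.10 to -0.00 in induced cells, from 0.05 to 0.17 for the average, from -0.35 to -0.08 for induction without Xrn1, from 0.28 to 0.08 for induction with Xrn1 and from 0.70 to 0.23 for the interaction.

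**Figure D1:**
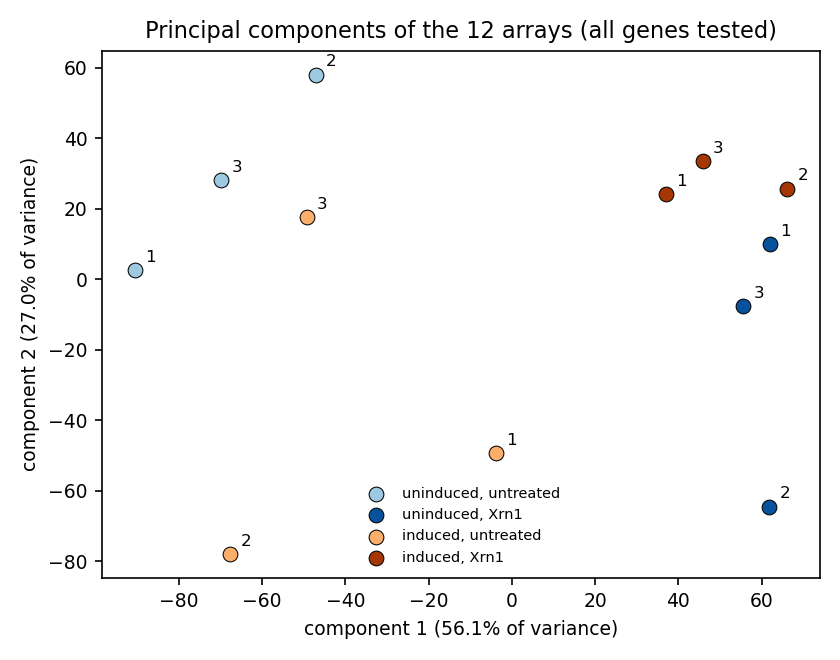
Scores of the 12 arrays on the first and second principal components of the gene values, which hold 56.1% and 27.0% of the variance, with 1 point per array and colours for the 4 groups. The Xrn1 and untreated arrays lie apart, and induced untreated replicate 3 lies among the uninduced untreated arrays.

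RNGTT, the gene of the capping enzyme itself, was measured by 24 probe sets. Its level was 4.00 ± 0.67 (SD, n = 3) in induced untreated samples and 3.79 ± 0.89 in uninduced untreated samples, and 2.48 ± 0.21 and 2.79 ± 0.43 in the induced and uninduced Xrn1 samples. Induction changed it by 0.21 without Xrn1, with a 95% confidence interval from -0.46 to 0.88 and a limma adjusted p of 0.685. Both rest on the common SD of 0.418 and not on the wider spread of RNGTT itself in these samples (0.67 and 0.89). The sources used here do not say whether these probe sets match the K294A transgene, so the level checks no label. Xrn1 changed RNGTT by -1.52 in induced cells (adjusted p = 0.000131) and by -1.01 in uninduced cells (adjusted p = 0.0112). The call in uninduced cells ended after centring (-0.65) and cyclic loess (-0.71), and without uninduced untreated replicate 1 (-0.76), uninduced untreated replicate 3 (-0.74) or uninduced Xrn1 replicate 1 (-0.80). With each gene's own spread neither call held (adjusted p = 0.0692 in induced and 0.159 in uninduced cells).

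Xrn1 in uninduced cells compares RNA with and without the enzyme where K294A was not induced. RMA normalises the arrays, so changes here are relative to the other RNAs measured, and a rise need not be a gain of RNA. A fall need not be removal by the enzyme, since an array effect that depends on intensity could not be told apart. The largest fall was that of SLC38A2, an amino acid transporter, from 8.63 ± 0.23 to 4.2 ± 0.50 (SD, n = 3), a change of -4.43 (adjusted p = 2.97e-34). ND4, a mitochondrially encoded subunit of complex I, fell from 10.34 ± 0.54 to 6.19 ± 0.27, and LPCAT3, a phospholipid acyltransferase, from 8.39 ± 0.31 to 4.26 ± 0.65. BMPR1A, a BMP receptor (-3.97), RNFT1 (-3.96), CLTC, the clathrin heavy chain (-3.90), EIF3L, a translation initiation factor subunit (-3.90), and HIF1A, the hypoxia transcription factor (-3.87), followed. Among the rises, MYADML2 rose by 2.01, ADAM5 by 1.91, the olfactory receptor pseudogene OR7A2P by 1.88 and the lectin CD302 by 1.81. Without the filter on dim probe sets, ADAM5 (0.72), OR7A2P (0.02) and CD302 (0.69) no longer passed, nor did OR7A2P with the median of its probe sets (0.31). With each gene's own spread, MYADML2 (adjusted p = 0.0683) and OR7A2P (0.0529) did not pass.

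Among the gene lists in uninduced cells, mRNAs of secretory and membrane proteins had the smallest camera p. Of 65 measured members, 60 fell and none rose, with a median of -2.15 (61 adjusted over the list alone). After cyclic loess 47 fell, with a median of -1.04. This list also holds 10 nuclear transport factors, which are neither secretory nor membrane proteins, and the largest falls were among them: the importins KPNA2 (-3.80), IPO7 (-3.56) and IPO5 (-3.52). The vesicle coat protein SEC23A fell by 3.41. Of the other 55 members 50 fell, with a median of -2.13. The camera adjusted p of all 65 was 5.34e-25, and the adjusted p = 0.286 with an estimated correlation. Of 51 mitotic genes, 45 fell (49 adjusted over the list alone; median -2.01), among them the kinase AURKA (-3.64), DLGAP5 (-3.38) and the kinesin KIF11 (-3.23). The camera adjusted p was 1.33e-18, and the adjusted p = 0.286 with an estimated correlation. After cyclic loess 34 mitotic genes fell, with a median of -1.14. All 9 measured mitochondrially encoded RNAs fell, by a median of -3.22, with ND2 at -3.73 and COX3, a subunit of cytochrome oxidase, at -3.44 (camera adjusted p = 5.07e-15; adjusted p = 0.218 with an estimated correlation). After cyclic loess 5 fell, with a median of -0.92. Translation factors fell in 15 of 16 (median -2.08; adjusted p = 0.286 with an estimated correlation), proteasome subunits in 29 of 31 (median -1.72; PSMA4 -3.52; adjusted p = 0.286 with an estimated correlation) and DNA replication genes in 36 of 43 (median -1.65; the primase subunit PRIM1 -3.03; adjusted p = 0.448 with an estimated correlation). After adjustment over the list alone, these counts were 15, 29 and 37. After cyclic loess 6 translation factors, 15 proteasome subunits and 22 DNA replication genes were lower, with medians of -0.34, -0.74 and -0.74. The 6 measured genes named in published work on cytoplasmic capping all fell, also when adjusted over the list alone, by a median of -2.56, with ITGB1, an integrin subunit, at -3.28 and VDAC3, a mitochondrial channel, at -3.06 (adjusted p = 0.286 with an estimated correlation). After cyclic loess 5 of these 6 fell, with a median of -1.15. That list was partly chosen on these samples and is not independent evidence.

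Ribosomal protein mRNAs in uninduced cells fell in 42 of 68 (44 adjusted over the list alone), with a median of -1.11, but cyclic loess turned that median to 0.44, with 26 higher and 0 lower. RPL4 fell by 2.11 and RPS4X by 2.08, and neither passed after cyclic loess (-0.03 and -0.40). The camera adjusted p of that list was 0.000189, and the adjusted p = 0.645 with an estimated correlation. Nuclear-encoded subunits of oxidative phosphorylation fell in 39 of 74 (40 adjusted over the list alone; median -0.85), and cyclic loess turned the median to 0.17, with 15 higher and 13 lower. ATP5F1B, an ATP synthase subunit, fell by 3.60. The camera adjusted p of the list was 0.00575, and the adjusted p = 0.645 with an estimated correlation. Replication-dependent histones fell in 5 of 12, also when adjusted over the list alone, with a median of -0.62 that cyclic loess turned to 0.58, with 4 higher and 0 lower. Of 17 markers of other cell types, only KRT18 (-1.52) and KRT8 (-1.46), keratins that U2OS cells can express, fell, and cyclic loess took KRT18 to -0.06, which did not pass, and turned KRT8 to 0.35. None of the 17 rose, but 3 were higher after centring and 3 after cyclic loess.

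In all, 6590 genes passed in uninduced cells (limma, Benjamini-Hochberg), of which 1223 were higher and 5367 lower. Centring gave 3930 higher of 8224 and cyclic loess 3695 higher of 7387. The median of probe sets gave 528 higher of 5795. Array weights, which stopped before they converged, gave 555 higher of 7171, and gene-by-gene weights 2671 of 10168. The 1223 higher genes became 469 without uninduced untreated replicate 2, 500 and 554 without uninduced Xrn1 replicates 2 and 3, and 278 without CM5 and CM5X. The 3 Xrn1 and 3 untreated values did not overlap for 44.8% of genes, where chance gives 10%.

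Xrn1 in induced cells makes the same comparison after K294A was induced. TMED7, a cargo receptor of the early secretory pathway, fell from 6.76 ± 0.70 to 3.11 ± 0.20 (SD, n = 3), a change of -3.65 (adjusted p = 2.32e-22). SLC38A2 fell by 3.51, the transporter ATP13A3 by 3.33, the membrane protein TM9SF3 by 3.32, BMPR1A by 3.20 and AZIN1, a regulator of polyamine synthesis, by 3.10. ZMPSTE24, the lamin protease, fell by 3.08 and PDIA6, an ER disulphide isomerase, by 3.07. Rises were led by OR7A2P (2.55), MYADML2 (2.55), the pseudogene ULK4P1 (2.51), the transcription factor SOX7 (2.33) and GLOD5 (2.15). With each gene's own spread, MYADML2 and SOX7 no longer passed (each adjusted p = 0.0586).

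Secretory and membrane protein mRNAs fell in 53 of 65 in induced cells and rose in 2 (56 and 2 adjusted over the list alone), with a median of -1.50. The ER chaperone HSP90B1 fell by 2.77, and of the nuclear transport factors KPNA2 by 2.89 and XPO1 by 2.76. Of the other 55 members 43 fell, with a median of -1.46. Mitotic genes fell in 41 of 51 (42 adjusted over the list alone; median -1.43), among them DLGAP5 (-2.37), the cyclin CCNB1 (-2.36), AURKA (-2.36) and ECT2 (-2.27). For both lists the adjusted p = 0.337 with an estimated correlation. All 9 mitochondrially encoded RNAs fell (median -1.78; adjusted p = 0.337 with an estimated correlation), while after cyclic loess 0 of 9 passed, with a median of -0.03. Translation factors fell in 13 of 16 (13 adjusted over the list alone; 7 after cyclic loess; adjusted p = 0.337 with an estimated correlation), proteasome subunits in 20 of 31 (22 adjusted over the list alone; adjusted p = 0.467 with an estimated correlation) and spliceosome and hnRNP proteins in 28 of 52, with 4 higher (also when adjusted over the list alone; adjusted p = 0.535 with an estimated correlation).

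Some lists went both ways in induced cells, where of all 16883 genes 3643 rose and 3000 fell. Among ribosomal protein mRNAs, 18 of 68 fell and 9 rose (18 and 10 adjusted over the list alone): RPL6 fell by 1.83, while RPS29 rose by 1.61 and RPL41 by 1.41. Their median was -0.30, and cyclic loess turned it to 0.45, with 32 higher and 2 lower. Of 74 oxidative phosphorylation subunits, 15 rose and 15 fell (17 and 16 adjusted over the list alone; 26 higher and 9 lower after cyclic loess). NDUFA3 and NDUFA13, small subunits of complex I, rose by 1.90 and 1.86, while NDUFA9 of the same complex fell by 2.01. Immediate early and short-lived mRNAs rose in 14 of 49 and fell in 4, the same counts as adjusted over the list alone. Markers of other cell types rose in 6 of 17 (4 adjusted over the list alone), among them GFAP of astrocytes (1.02) and SYP of neurons (1.01). Neither passed without induced untreated replicate 2 (0.61 and 0.72). GFAP also failed without induced Xrn1 replicate 3 (0.96), and SYP without induced Xrn1 replicate 2 (1.00) or 3 (0.99).

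In induced cells, 6643 genes passed (limma, Benjamini-Hochberg), 3643 higher and 3000 lower, and 50.9% of genes had values that did not overlap, where chance gives 10%. More were lower than higher with the median of probe sets (2186 higher, 2599 lower), without the filter on dim probe sets (2582 and 2892) and after centring (3665 and 3871). Cyclic loess gave 3943 higher and 3698 lower. Without induced untreated replicate 2 the count was 2395 and most were lower (564 higher, 1831 lower). It was 4007 without induced Xrn1 replicate 2 (2076 higher, 1931 lower), 4191 without induced Xrn1 replicate 3 (1905 higher, 2286 lower), and 1492 with each gene's own spread (455 higher, 1037 lower). Between the uninduced and the induced samples, 2438 genes were lower in both, where 953.7 are expected by chance, 91 were higher in both (263.9 expected), and 59 passed with opposite signs. Across genes, the Xrn1 effects in the 2 sets of arrays correlated at 0.595.

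Averaged over both induction states, SLC38A2 changed by -3.97 ± 0.24 (SE; adjusted p = 1.73e-56), TMED7 by -3.69, BMPR1A by -3.58, TM9SF3 by -3.47, CLTC by -3.47, AZIN1 by -3.46, LPCAT3 by -3.35 and KPNA2 by -3.34. The calmodulin gene CALM3 rose by 1.5 ± 0.24 (SE; adjusted p = 5.67e-09) and PROK2, a secreted peptide, by 1.40. MYADML2 rose by 2.28, OR7A2P by 2.22, C1QTNF9 by 1.77, SOX7 by 1.77, the mitochondrial deformylase PDF by 1.48 and the defensin-like SPAG11B by 1.43. Without the filter on dim probe sets, OR7A2P (0.41) and C1QTNF9 (0.37) no longer passed. XRN1, which encodes the cellular form of the enzyme, changed by -1.02 (adjusted p = 0.000128) and RPLP0, a ribosomal protein, by -1.21 (adjusted p = 3.67e-06), which cyclic loess turned to 0.54. BOP1, a ribosome biogenesis factor, was at 0.35 (adjusted p = 0.218).

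**Figure D2:**
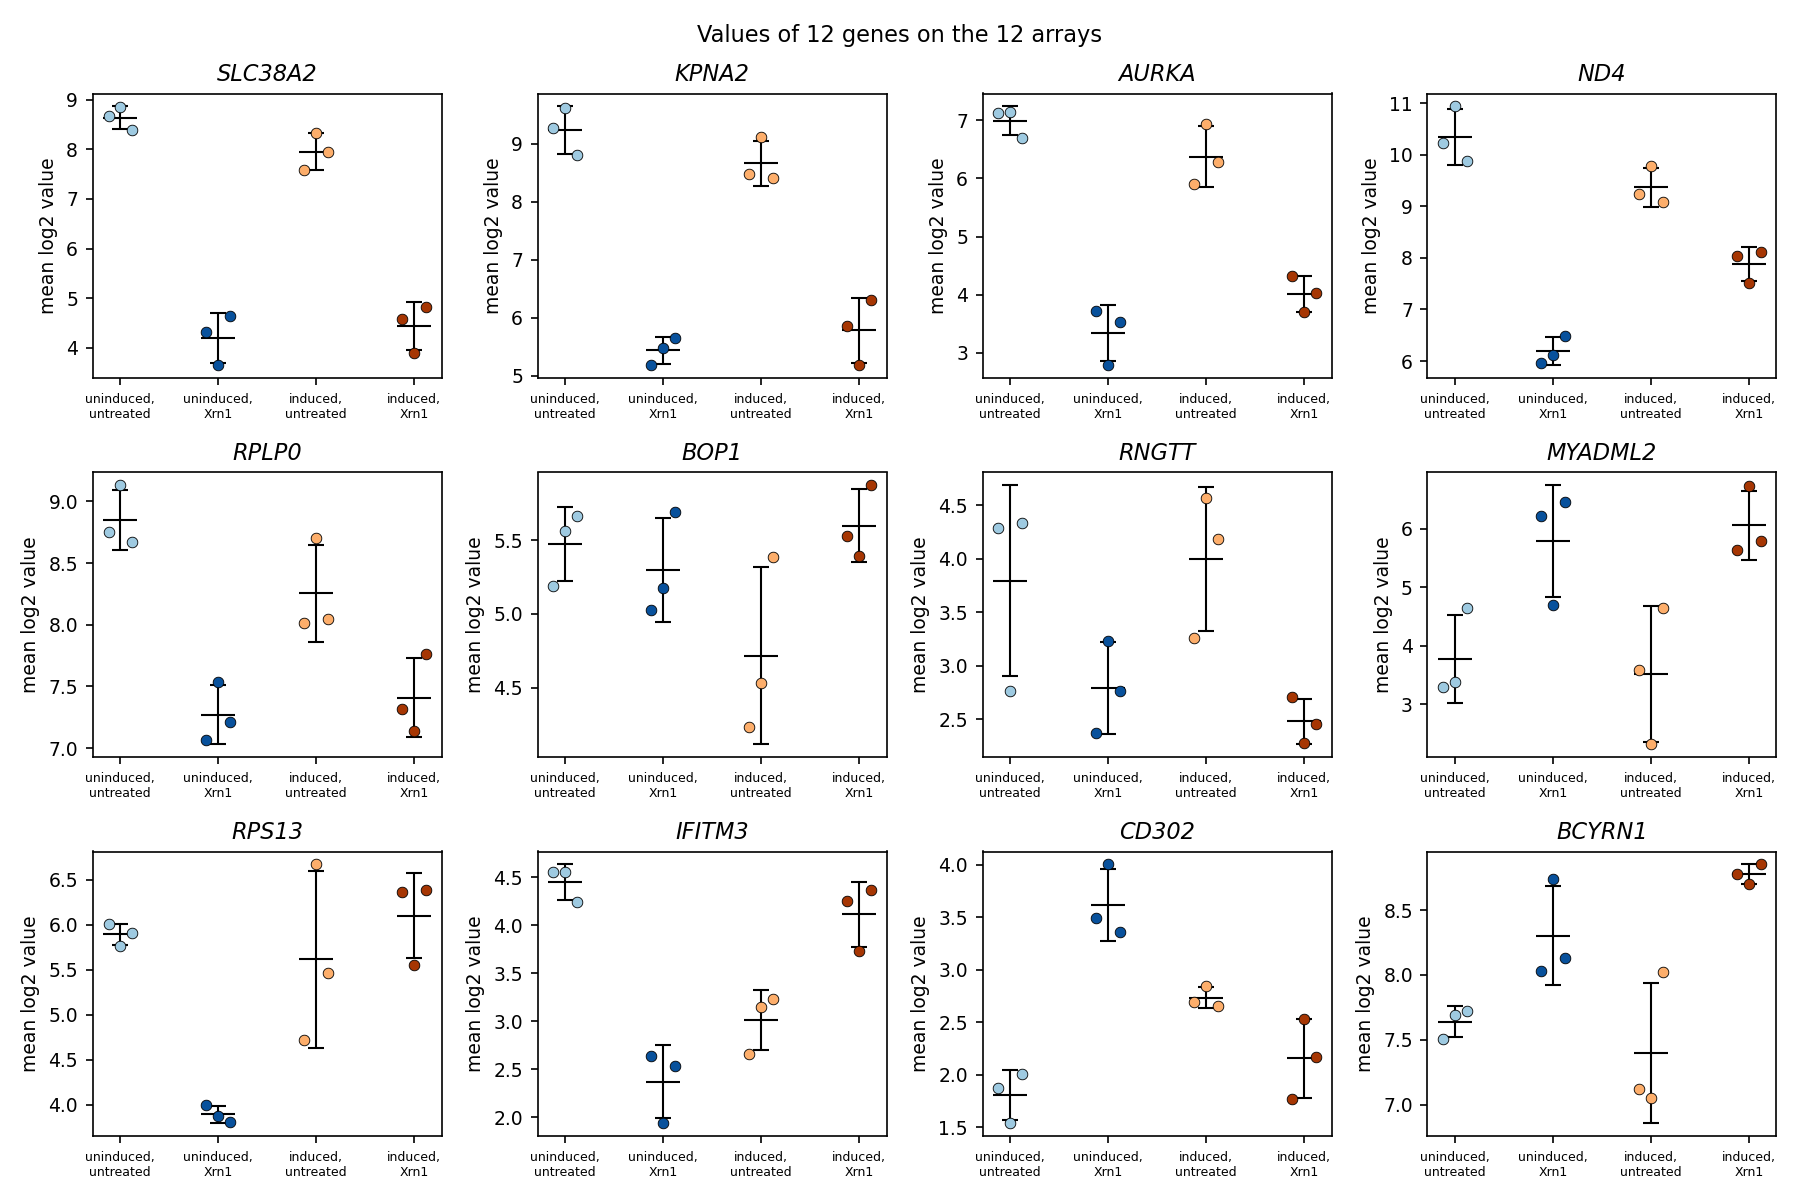
Log2 levels of 12 genes in the 4 groups, with 1 point per array and bars for the mean ± SD of 3 arrays. SLC38A2 lies near 8.63 and 7.95 in uninduced and induced untreated samples and near 4.2 and 4.44 after Xrn1, while MYADML2 is higher after Xrn1.

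Of the 65 secretory and membrane protein mRNAs, 59 fell on average (60 adjusted over the list alone; median -1.96; 49 of 55, with a median of -1.67, without the nuclear transport factors), and of 51 mitotic genes 45 (47 adjusted over the list alone; median -1.79), with TOP2A, a topoisomerase, at -2.63 and the kinesin KIF23 at -2.62. Both lists kept negative medians after centring (-1.84 and -1.66) and cyclic loess (-1.29 and -1.39). Their camera adjusted p were 2.88e-32 and 3.34e-23, and for both the adjusted p = 0.209 with an estimated correlation. All 9 mitochondrially encoded RNAs fell (median -2.54; CYTB -2.60; adjusted p = 0.209 with an estimated correlation). After cyclic loess 4 did, with a median of -0.34 and CYTB at -0.28, which did not pass. Among the other lists, 35 of 43 DNA replication genes fell (the ribonucleotide reductase subunit RRM1 -2.40), 28 of 31 proteasome subunits (PSMA6 -2.56), 15 of 16 translation factors (EIF3E -2.51), 40 of 52 spliceosome and hnRNP proteins, 31 of 53 genes of decapping and cytoplasmic mRNA decay, 23 of 39 genes of the integrated stress response and 7 of 9 genes of the capping enzyme and cap methylation (the cap methyltransferase RNMT -2.39, the cap-binding NCBP1 -1.80). Adjusted over the list alone, these counts were 35, 28, 15, 41, 32, 23 and 8. After cyclic loess they were 26, 18, 9, 25, 29, 18 and 7, and the medians of translation factors and spliceosome proteins went from -1.78 and -1.02 to -0.43 and -0.41. With an estimated correlation, their adjusted p were 0.388, 0.255, 0.209, 0.388, 0.497, 0.388 and 0.388. The 6 measured genes of published work on cytoplasmic capping, in part chosen on these samples, all fell (6 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation).

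The remaining lists moved less on average or turned with the scaling. Ribosomal protein mRNAs fell in 37 of 68 and rose in 3 (40 and 3 adjusted over the list alone; median -0.74), and cyclic loess turned the median to 0.47, with 34 higher and 2 lower. RPL6 fell by 1.91 and RPL9 by 1.61, which did not pass after cyclic loess (-0.36; camera adjusted p = 0.00305; adjusted p = 0.653 with an estimated correlation). Of the nuclear retained RNAs, a marker of nuclear RNA in the extract, 7 of 15 fell, among them TUG1 (-2.75) and MALAT1 (-2.30), and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0264; adjusted p = 0.458 with an estimated correlation). Camera did not call the other 9 lists. Of these, oxidative phosphorylation had 29 of 74 lower and 5 higher (29 and 5 adjusted over the list alone; the median of -0.25 turned to 0.18 after cyclic loess), extracellular matrix and bone 15 of 31 lower and 6 higher (16 and 6; -0.53 turned to 0.30), ZNF-named zinc finger genes 67 of 211 lower and 10 higher (63 and 10), p53 targets 10 of 25 lower and 1 higher (10 and 1), and histones 5 of 12 lower (5; -0.50 turned to 0.26). The snoRNA host genes had 6 of 15 lower (6; -0.18 turned to 0.02), immediate early mRNAs 8 of 49 lower and 8 higher (8 and 8), type I interferon genes 5 of 38 lower and 7 higher (5 and 7), and markers of other cell types 2 of 17 lower and 1 higher (2 and 0). These counts depend on the scaling. Immediate early mRNAs had 16 higher and 7 lower after centring and 21 and 2 after cyclic loess, interferon genes 14 and 4, then 11 and 6, and markers of other cell types 7 and 2, then 7 and 0. Oxidative phosphorylation had 11 higher and 27 lower after centring and 27 and 14 after cyclic loess, extracellular matrix and bone 11 and 15, then 9 and 8, ZNF-named genes 21 and 63, then 21 and 88, p53 targets 4 and 10, then 6 and 8, histones 1 and 5, then 4 and 2, and snoRNA host genes 2 and 6 each time. None of the 22 lists passed camera with an estimated correlation in any of the 6 comparisons. Camera with the preset correlation called 14, 13, 13, 3, 4 and 4 lists in the order of the comparisons, and fry 18, 11, 18, 0, 0 and 0.

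**Figure D3:**
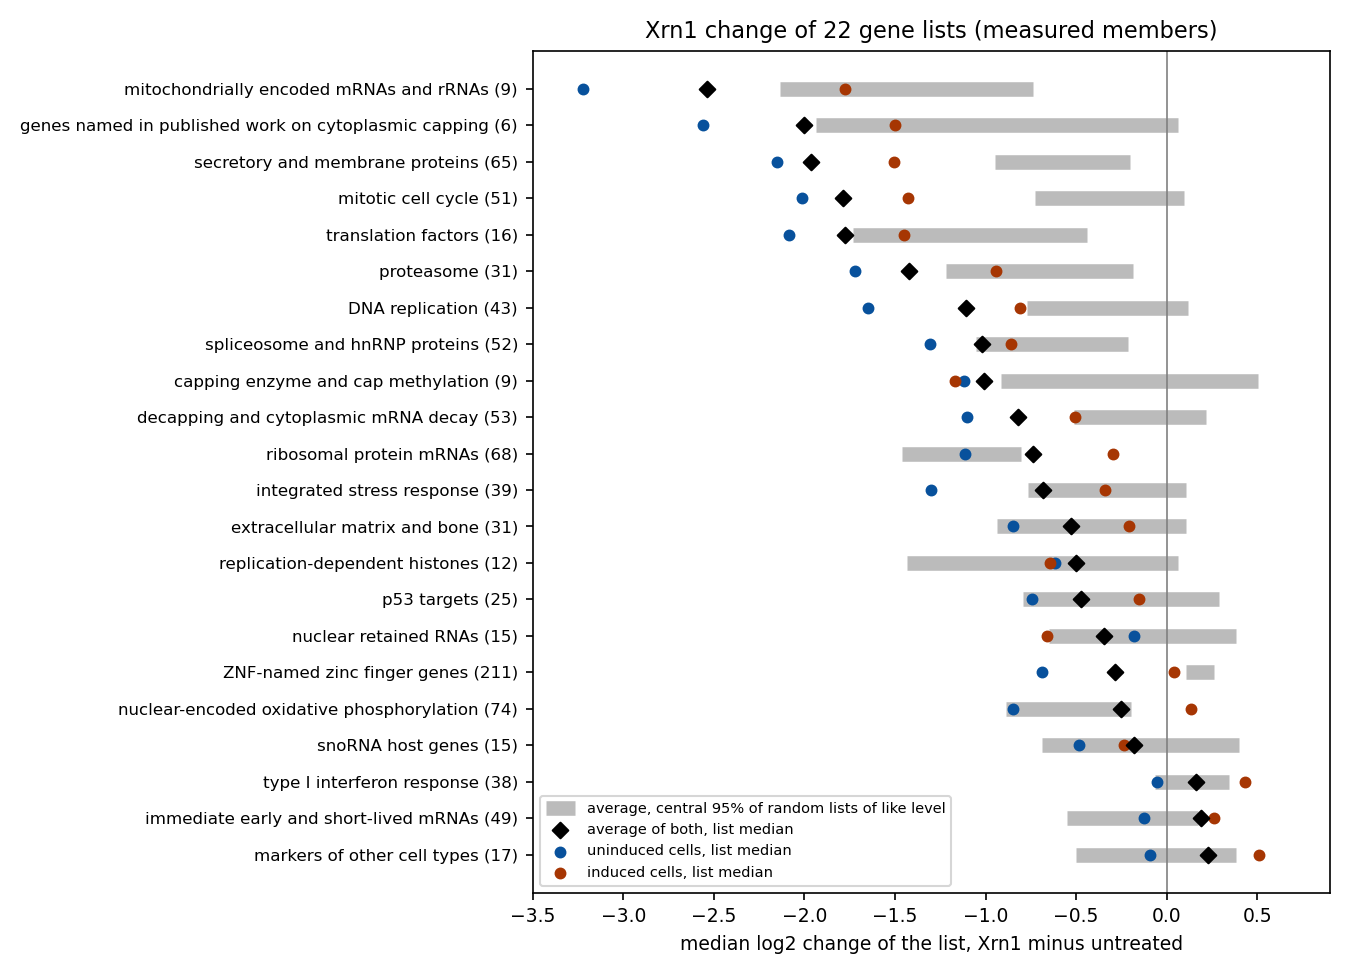
Median log2 change after Xrn1 of each gene list in uninduced cells, in induced cells and on average (points), with grey bars for the central 95% of random lists of the same size and level. The secretory and mitotic lists lie left of their bars on average, at -1.96 and -1.79, and the ribosomal protein list at -0.74 lies right of its bar. Of the 22 lists, 10 lie left of their bars on average and 2 right. Cyclic loess turned the ribosomal protein median to 0.47.

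On average, 7422 genes passed (limma, Benjamini-Hochberg), 2391 higher and 5031 lower, of which 6920 changed by at least 1.5 times. Centring gave 5361 higher of 10248 and cyclic loess 4644 higher of 9145. The median of probe sets gave 1059 higher of 5919, and no filter on dim probe sets 1239 higher of 6146. The 2391 higher genes became 1328 without induced untreated replicate 2, 1348 without uninduced Xrn1 replicate 3, 1470 and 1478 without induced Xrn1 replicates 3 and 2, 1564 without uninduced untreated replicate 1 and 3936 without induced untreated replicate 3. Falls were larger in genes with higher levels: the median change in uninduced and induced cells was 0.06 and 0.09 in the 5035 genes under a mean of 3, -0.85 and -0.04 in the 2900 genes from 4 to 5, and -1.96 and -1.43 in the 79 genes over 7. Of the 1063 genes above 5, 726 (68.3%) were lower and 71 higher. Cyclic loess, which adjusts the arrays at each level, took this trend out: over 7 the medians were 0.11 and -0.01, and of the 1063 genes 350 were lower and 368 higher.

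**Figure D4:**
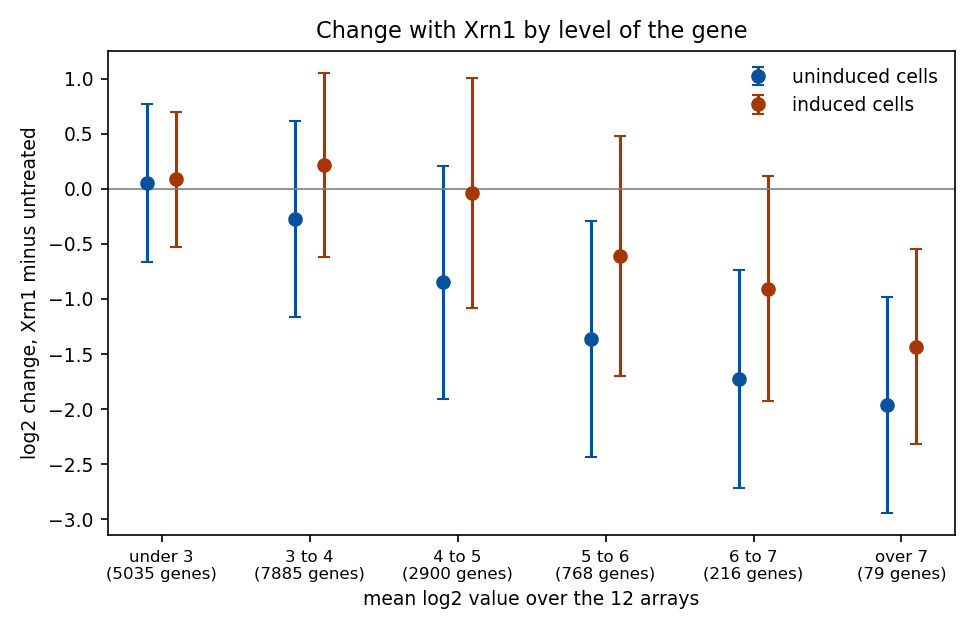
Median log2 change after Xrn1 by mean level of the gene over the 12 arrays, in uninduced and induced cells (points), with bars for the SD over genes. The medians go from 0.06 and 0.09 under a level of 3 to -1.96 and -1.43 over 7.

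Induction without Xrn1 compares steady levels with and without doxycycline, which induces K294A. Every induced sample received doxycycline and no uninduced one did. The drug itself and K294A therefore cannot be told apart, here, with Xrn1 or in the interaction. IFIT5, an interferon-induced RNA-binding protein, was at 2.56 ± 0.78 (SD, n = 3) with induction and 4.01 ± 0.50 without, a change of -1.46 (adjusted p = 0.0488). MAP1LC3B2, an autophagy protein, changed by -1.54, the myosin light chain MYL2 by -1.49 and the phosphatase NUDT11 by -1.49 (each adjusted p = 0.0458). The other 3 genes that passed, chosen after their values were seen, were OR2F2 (1.51), LOC100130452 (1.66) and RNF2P1 (-1.46). IFIT5, MAP1LC3B2 and NUDT11 passed only without induced untreated replicate 3 or uninduced Xrn1 replicate 2 when 1 array was left out, and MYL2 also without induced untreated replicate 2. Where the calls ended, the changes were -1.68 to -1.05 for IFIT5, -1.61 to -1.32 for MAP1LC3B2, -1.71 to -1.20 for NUDT11 and -1.75 to -1.09 for MYL2. Camera called 3 lists, all lower: ZNF-named genes (median -0.65; adjusted p = 0.000546), oxidative phosphorylation (-0.51; adjusted p = 0.0380) and DNA replication (-0.66; adjusted p = 0.0380). The median of all genes was -0.35. After centring the medians of the 3 lists were -0.38, -0.24 and -0.40, and after cyclic loess -0.53, -0.10 and -0.24. No member of these lists passed over all genes. Adjusted over the list alone 23, 17 and 2 were lower. For each list the adjusted p = 0.992 with an estimated correlation. ND4 was at -0.98 (adjusted p = 0.110) and the mitotic KIF11 at -1.02 (adjusted p = 0.110).

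In all, 7 genes passed without Xrn1 (limma, Benjamini-Hochberg), 2 higher and 5 lower, and 5201 had an unadjusted p under 0.05. The values did not overlap for 23.2% of genes, where chance gives 10%. Without induced untreated replicate 3, which matched the uninduced untreated arrays more closely than its own group, 6922 genes passed, 517 higher and 6405 lower. No value here checks whether that array came from induced cells, so both counts rest on its label. Induced untreated replicate 2 also correlated more with an uninduced untreated array (0.894) than within its group (0.888 at most), so 6922 is not a cleaner count. Of 100 simulated draws without an effect, 9 called as many genes as the real 7, and the highest called 8083. The count was 0 without induced untreated replicate 1, any of the 3 induced Xrn1 replicates, uninduced untreated replicate 1 or 2, or uninduced Xrn1 replicate 3. It was 1 without uninduced untreated replicate 3 or uninduced Xrn1 replicate 1, and 3 without induced untreated replicate 2. It was 0 after cyclic loess and with each gene's own spread, and after centring 18 of 18 were higher.

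Induction with Xrn1 compares RNA left after the enzyme, which is meant to spare RNAs with a protected 5' end. No value here measures how complete the digestion was, or whether it was equal in induced and uninduced samples. That limits the interaction as well. RPS13, a ribosomal protein, was at 6.10 ± 0.47 (SD, n = 3) with induction and 3.89 ± 0.10 without, a change of 2.21 (adjusted p = 1.80e-06). RPL41, another ribosomal protein, changed by 1.75 and IFITM3, an interferon-induced membrane protein, by 1.74 (each adjusted p = 0.00184), ND4 by 1.70 (adjusted p = 0.00292) and IFITM2 by 1.57 (adjusted p = 0.0137). RTL8A (1.53), TMEM258 of the oligosaccharyltransferase (1.5) and the small heat shock protein HSPB8 (1.45) were also higher and CD302 lower (-1.46). The remaining gene that passed was UXT (1.43), chosen after its values were seen. RPL41 no longer passed without induced Xrn1 replicate 1 (1.80) or 3 (1.54) or uninduced Xrn1 replicate 1 (1.60), IFITM3 without induced Xrn1 replicate 1 (1.68) or 3 (1.62) or uninduced Xrn1 replicate 2 (1.53), and ND4 without induced Xrn1 replicate 1 (1.62) or 3 (1.58) or uninduced Xrn1 replicate 1 (1.58) or 2 (1.66). IFITM2, RTL8A, TMEM258, HSPB8 and CD302 each failed without any 1 of the 3 induced Xrn1 arrays, uninduced Xrn1 replicate 2 or uninduced untreated replicate 2, with changes of 1.22 to 1.64, 1.33 to 1.72, 1.23 to 1.66, 1.36 to 1.57 and -1.65 to -1.27 over all arrays whose loss ended the call. These also include induced untreated replicate 3 (not for HSPB8), uninduced Xrn1 replicate 1 (not for IFITM2), uninduced Xrn1 replicate 3 (TMEM258, HSPB8 and CD302) and uninduced untreated replicate 3 (HSPB8 and CD302). Camera called ribosomal protein mRNAs (median 0.37, 2 of 68 higher, 4 adjusted over the list alone; adjusted p = 0.00242), oxidative phosphorylation (0.44, 0 of 74, 9 adjusted over the list alone; adjusted p = 0.000879), mitochondrially encoded RNAs (0.88, 1 of 9, 5 adjusted over the list alone; adjusted p = 6.11e-05) and, lower, histones (-0.36, 0 of 12 either way; adjusted p = 6.11e-05). For all 4 lists the adjusted p = 0.999 with an estimated correlation. After centring their medians were 0.17, 0.24, 0.68 and -0.56, and after cyclic loess 0.07, 0.09, 0.71 and -0.58. The median of all genes was 0.28 before either.

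With Xrn1, 10 genes passed (limma, Benjamini-Hochberg), 9 higher and 1 lower, and 1534 had an unadjusted p under 0.05. The values did not overlap for 34.4% of genes, where chance gives 10%. The count was 1 without induced Xrn1 replicate 1 or 3, 2 without uninduced Xrn1 replicate 2, 3 without uninduced Xrn1 replicate 1, 4 without induced Xrn1 replicate 2 or uninduced untreated replicate 2, 5 without induced untreated replicate 3 and 6 without uninduced Xrn1 replicate 3. RPS13 passed whichever single array was left out. Centring gave 3 higher of 4, cyclic loess 4 higher of 5, each gene's own spread 0 of 0, and a fit of only the Xrn1 arrays 991 higher of 1034. Across genes, the induction effects without and with Xrn1, on separate arrays, correlated at -0.781.

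The interaction asks which RNAs Xrn1 lowered more, or less, once K294A was induced with doxycycline. A positive value means a higher Xrn1 effect in induced cells, that is a smaller fall, or a rise. IFITM3 had the largest difference, 3.18 ± 0.48 (SE; adjusted p = 7.73e-07): Xrn1 took it from 4.45 ± 0.18 to 2.37 ± 0.38 (SD, n = 3) in uninduced cells, and it was 3.02 ± 0.31 and 4.11 ± 0.34 in induced cells. ND4 differed by 2.67 (adjusted p = 0.000265), TMEM258 by 2.64, ULK4P1 by 2.56, MRPS12 of the mitochondrial ribosome by 2.50, RPS13 and RPL41 by 2.48 and TMEM179B by 2.47. On the negative side were CD302 (-2.39, adjusted p = 0.00116), the olfactory receptor OR2F2 (-2.34), the drug-metabolising CYP3A4 (-2.16), CD200R1L (-2.13), PXT1 (-1.94), the protease ADAMDEC1 (-1.88), the chaperone DNAJB8 (-1.72) and GBP4 (-1.71), all dim genes with means under 4 in each group. Without induced untreated replicate 1, CD200R1L (-1.69), PXT1 (-1.75), ADAMDEC1 (-1.70), DNAJB8 (-1.53) and GBP4 (-1.51) no longer passed. The same 5 did not pass without induced Xrn1 replicate 3 (-1.98, -2.0, -1.85, -1.80 and -1.66). The last 4 did not without uninduced Xrn1 replicate 2 (-1.76, -1.77, -1.68 and -1.59), and the last 3 without induced Xrn1 replicate 1 (-1.83, -1.64 and -1.69). Without CM5 and CM5X, only IFITM3 still passed (2.91, adjusted p = 0.0333).

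Among the lists, camera called mitochondrially encoded RNAs (median 1.67, 5 of 9 higher, 5 adjusted over the list alone; adjusted p = 0.0103), oxidative phosphorylation (1.02, 26 of 74 higher, 32 adjusted over the list alone; NDUFA3 2.36; adjusted p = 0.0103), ZNF-named genes (1.00, 53 of 211 higher and 1 lower, 79 and 2 adjusted over the list alone; adjusted p = 0.0164) and ribosomal protein mRNAs (0.74, turned to -0.01 by cyclic loess; 16 of 68 higher, 19 adjusted over the list alone; RPS29 2.06; adjusted p = 0.0223). For all 4 lists the adjusted p = 0.980 with an estimated correlation. After centring the members that passed were 4, 15, 5 and 3 higher, with 6 ZNF-named genes lower, and after cyclic loess 2, 3, 8 and 2 higher, with 2 ZNF-named genes lower. Secretory and membrane protein mRNAs had 13 of 65 higher (median 0.50, turned to -0.14 by cyclic loess) and mitotic genes 12 of 51 (median 0.87). Camera called neither (adjusted p = 0.530 and 0.471). Adjusted over the list alone, 17 and 14 were higher, and after centring 3 and 1, after cyclic loess 0 and 0. RNGTT differed by -0.52 (adjusted p = 0.405).

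For the interaction, 3687 genes passed (limma, Benjamini-Hochberg), 3479 higher (94.4%) and 208 lower. Of the 3479, the Xrn1 effect was negative in both states for 1160, negative in uninduced and positive in induced cells for 2196, and positive in both for 123. The median of probe sets gave 1465 genes, probe sets above the upper quartile 1165 and 1 probe set per gene 2360. The replicate number as a block gave 145 genes, and the number as printed in the titles gave 2793. Centring gave 520 higher of 1856 (28.02%) and cyclic loess 165 higher of 423. Without induced untreated replicate 3, whose label could not be checked, the count was 8400. It was 50 without induced Xrn1 replicate 3, 64 without uninduced Xrn1 replicate 2, 100 and 126 without induced untreated and induced Xrn1 replicate 1, 731 without uninduced untreated replicate 3, 1400 and 1466 without induced untreated and induced Xrn1 replicate 2, 2039 without uninduced Xrn1 replicate 3 and 2093 without uninduced untreated replicate 2. With each gene's own spread 0 passed, against 7210 at an unadjusted p under 0.05 with the common spread.

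On single probe sets, without a summary by gene, Xrn1 changed 129615 of 705699 in uninduced cells (53212 higher), 87543 in induced cells (48601 higher) and 162691 on average (82352 higher). Induction changed 0 without Xrn1 (limma; 96687 at an unadjusted p under 0.05) and 42 with Xrn1 (41 higher), and 64 differed in the Xrn1 effect (45 higher).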

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

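The tests of gene size, of cyclic loess on the level trend, of level alone and of the median difference without CM5 and CM5X were chosen after the data had been seen, as were each gene's own spread and the loss of CM5 and CM5X, and the 3 patterns weighed here were noticed in the same data. The difference in the Xrn1 effect between uninduced and induced cells is listed here because it parts the groups: 3687 genes and 64 probe sets passed. The genes with the largest differences were IFITM3 (3.18), ND4 (2.67), TMEM258 (2.64), ULK4P1 (2.56), MRPS12 (2.50), RPS13 (2.48), RPL41 (2.48) and TMEM179B (2.47) on the positive side. On the negative side they were CD302 (-2.39), OR2F2 (-2.34), CYP3A4 (-2.16), CD200R1L (-2.13), PXT1 (-1.94), ADAMDEC1 (-1.88), DNAJB8 (-1.72) and GBP4 (-1.71). Gene lists called by camera had medians of 1.67 (mitochondrially encoded RNAs), 1.02 (oxidative phosphorylation), 0.74 (ribosomal protein mRNAs, turned to -0.01 by cyclic loess) and 1.00 (ZNF-named genes), and none was called with an estimated correlation. A signal also lies in probe sets without exactly 1 gene symbol: Xrn1 on average changed 74561 of 447524 (16.7%), 60916 higher and 13645 lower. With 1 symbol it changed 88130 of 258175 (34.1%), mostly the other way, 21436 higher and 66694 lower.

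For most genes called, the Xrn1 effect was higher in induced cells (94.4% of 3687). A shift shared by whole arrays cannot be told apart from a change shared by most mRNAs, since centring takes the same 0.465 from every gene and thereby sets the share of higher calls (28.02%). Without CM5 and CM5X the median difference over all 16883 genes was 0.62, against 0.70. This argues against that pair as the whole source of the shift over all genes. It does not tell what sets the differences of single genes. Without the pair 1 gene passed, a fall in count that was predicted beforehand if the spread of these arrays were the source. That count decides nothing, as 2 passed without CM1 and CM1X. Without the pairs of CM2, CM3, CM4 and CM6 the counts were 604, 6636, 4384 and 91. Whether array noise shared by genes is the source cannot be decided. Of 100 draws without an effect 2% called as many genes, the highest 4573. The draws gave all groups the same spread. The real groups differed, with correlations of 0.711 to 0.918 within uninduced Xrn1 and 0.942 to 0.959 within induced Xrn1. The induction of K294A, the biological difference that the design names, stays open for IFITM3, together with the doxycycline used. This gene passed without CM5 and CM5X (2.91, limma adjusted p = 0.0333) but not with its own spread (adjusted p = 0.0925). Its difference was positive: it was lower after Xrn1 in uninduced cells and higher in induced cells. That direction is opposite to the larger fall that RNA with more 5' ends open to Xrn1 would show. It therefore does not mark IFITM3 as an RNA that lost re-capping.

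Xrn1 lowered genes by more the higher their level. The changes left after removal of the level trend correlated at 0.850 between the uninduced and the induced arrays, over genes with a mean above 5. This argues against the same measured change for all genes of like level. Whether the loss of RNA itself was uniform cannot be decided. Genes of like mean can differ in how many of their probe sets are dim, and dim probe sets can fall little. CM5 and CM5X are argued against as the cause, since without them the median average change of those genes was -1.14, against -1.13 with all arrays. An array effect that depends on intensity cannot be told apart from a real trend with level, since cyclic loess takes out either and left a median of -0.011 for those genes. Gene size stays open, as the detrended change fell with the number of probe sets (Spearman rho = -0.347), and a difference between RNAs in how many 5' ends are open to Xrn1 was not tested apart from size.

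Secretory mRNAs (10 of the 65 encode nuclear transport factors) and mitotic mRNAs had the smallest camera p of the lists lowered by Xrn1 on average, though not the lowest medians, and the adjusted p = 0.209 with an estimated correlation for both. Level alone is argued against for both only as far as genes vary independently. Among 10000 random lists of like level, their medians stood at percentile 0. This was not particular to them: of the 22 lists, 10 lay below the central 95% on average and 2 above. ZNF-named genes also stood at percentile 0, genes of decapping and mRNA decay at 0.02 and DNA replication genes at 0.05. The median of ribosomal protein mRNAs, whose direction cyclic loess turns, stood at 99.2. The random lists drew genes independently, while correlations estimated within lists were 0.183 to 0.656, so these percentiles are too extreme. The lists drawn were also not matched on the number of probe sets. For mitochondrially encoded RNAs level alone stays open, since their median stood at percentile 0.3 on average but at 6.54 in induced cells, within the central 95%. No biological explanation was tested, and the normalisation within RMA cannot be examined without raw intensities, which were not used here.

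Other splits of the arrays were fitted for each count. In uninduced cells 1 of 10 splits gave as many genes as the real 6590 (highest other 0), in induced cells 1 of 10 (real 6643, highest other 0) and for induction with Xrn1 1 of 10 (real 10, highest other 0). For induction without Xrn1 it was 3 of 10 (real 7, highest other 308), and the split with 308, which joins uninduced untreated replicate 1 to induced untreated replicates 1 and 2, points to a structure of the samples. With 10 splits the share is never under 0.1. For the average only the real split among 100 gave as many (real 7422, highest other 4678), a share under 0.05. This argues against chance and does not exclude it. For the interaction it was 2 of 100 (real 3687, highest other 5495), a share under 0.05, but the split with 5495, which swaps induced untreated replicate 3 with uninduced untreated replicate 1, gave more genes than the real one and points to a structure of the samples. In simulated draws without an effect, as many genes as the real count were called in 0 of 100 for each of the 3 Xrn1 comparisons, in 9 for induction without Xrn1, in 1 for induction with Xrn1 and in 2 for the interaction. The highest draw called 6366 genes for Xrn1 in induced cells, close to the real 6643. It called 3483 in uninduced cells and 4071 on average.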

How the results depend on the processing

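Each gene's own spread, the loss of CM5 and CM5X, genes with a mean above 5 and gene-by-gene array weights were chosen after the data had been seen. Over all settings, fixed before or chosen after, of 11807 values of named genes 10778 kept their side of the threshold, 690 were weaker, 322 stronger and 17 reversed. Among the 10778, values called in both fits had the same direction by definition. A changed direction was counted as reversed where either fit called the gene, and was not compared for genes called in neither. On average RN7SK and RPLP0 passed both in the main fit and after cyclic loess, with opposite signs. The 437 values with a fold of at least 1.5 come from the main fit itself, so they were kept by construction. The total Xrn1 counts in uninduced cells and on average, though not their higher genes alone, stayed within 1.5 times of 6590 and 7422 when any 1 array was left out (5144 to 7278 and 5918 to 8613), and the counts for induction and for the interaction did not. The array signal limits what can be told of dim genes, and comparisons of the 5' and 3' parts of genes were not run. Default array weights stopped before they converged in all 6 fits. Correlations of the 6 CM pairs were -0.44, -0.40, 0.13, -0.55, -0.71 and -0.24, and 2 of 12 arrays matched best with their own number. These values do not decide whether an array and its Xrn1 partner came from the same RNA, since each group holds few arrays. A pairing by sample number therefore stays open.

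The cause was not tested for any change below, other than fewer arrays or genes where some were left out. For induction without Xrn1 (7 genes), the median of probe sets gave 0, probe sets above the upper quartile 0, 1 probe set per gene 37, centring 18, cyclic loess 0, array weights 5390, gene-by-gene weights 4742, only the groups compared 0, the replicate block 1, the block as printed in the titles 1, own spread 0, no CM5 and CM5X 0, and a mean above 5 gave 3. For a count of 0, limma had 5201 at an unadjusted p under 0.05 with all arrays. For induction with Xrn1 (10 genes, 1534 at an unadjusted p under 0.05), these were 6 (median), 4 (upper quartile), 4 (centring), 5 (cyclic loess), 257 and 6400 (weights), 1034 (only the groups compared), 3 (block as printed in the titles), 0 (own spread), 0 (no CM5 and CM5X) and 19 (mean above 5). For the interaction (3687 genes, 7210 at an unadjusted p under 0.05), they were 1465 (median), 1165 (upper quartile), 2360 (1 probe set), 1856 (centring), 423 (cyclic loess), 7229 and 8622 (weights), 145 (replicate block), 0 (own spread), 1 (no CM5 and CM5X) and 336 (mean above 5). Xrn1 in uninduced cells gave 10168 with gene-by-gene weights and 850 of 1063 genes with a mean above 5. In induced cells own spread gave 1492 and a mean above 5 gave 682, and on average a mean above 5 gave 841. With the replicate block, the higher genes alone were 716 in uninduced cells and 1542 on average.

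Leaving out 1 array gave 2395 to 7979 genes for Xrn1 in induced cells (2395 without induced untreated replicate 2, 4007 and 4191 without induced Xrn1 replicates 2 and 3). Induction without Xrn1 ranged from 0 (without induced untreated 1, induced Xrn1 1, 2 or 3, uninduced untreated 1 or 2, or uninduced Xrn1 3) through 1 (uninduced Xrn1 1 or uninduced untreated 3) and 3 (induced untreated 2) to 6922 (induced untreated 3). Induction with Xrn1 ranged from 1 (induced Xrn1 1 or 3) to 14, with 2 (uninduced Xrn1 2), 3 (uninduced Xrn1 1), 4 (induced Xrn1 2 or uninduced untreated 2), 5 (induced untreated 3) and 6 (uninduced Xrn1 3). The interaction ranged from 50 (induced Xrn1 3) to 8400 (induced untreated 3), with 64 (uninduced Xrn1 2), 100 (induced untreated 1), 126 (induced Xrn1 1), 731 (uninduced untreated 3), 1400 (induced untreated 2), 1466 (induced Xrn1 2), 2039 (uninduced Xrn1 3) and 2093 (uninduced untreated 2).

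All 17 reversals came with cyclic loess. In uninduced cells they were H1-4 (0.69), H2AC21 (0.46), H2AC20 (0.88), KRT8 (0.35), RN7SK (2.42), BOP1 (1.14) and RPLP0 (0.54), in induced cells H2AC20 (0.16), RN7SK (0.97) and RPLP0 (0.54), and on average H1-4 (0.25), H2AC21 (0.038), H2AC20 (0.52), RN7SK (1.70), KRT8 (0.48), KRT18 (0.12) and RPLP0 (0.54). For probe sets, induction without Xrn1 (0) gave 1 without the filter and 3 with a trended and robust prior, induction with Xrn1 (42) gave 101 with that prior, and the interaction (64) gave 779 without the filter, 20 above the upper quartile, 166 with the replicate block and 231 with that prior. For gene lists, an estimated correlation gave 0 in all 6 comparisons and fry 0 for both inductions and the interaction. The median of probe sets gave 1 list for the interaction, cyclic loess 1 and 2 for induction without and with Xrn1, and the loss of CM5 and CM5X gave 6 for induction without Xrn1.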

Other observations

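The 7 genes at the end of this part were chosen after their values were seen. BCYRN1, a small cytoplasmic RNA made by RNA polymerase III, was at 7.64 ± 0.12 and 8.30 ± 0.38 (SD, n = 3) without and with Xrn1 in uninduced cells and at 7.40 ± 0.54 and 8.78 ± 0.07 in induced cells. It rose by 1.38 in induced cells (limma adjusted p = 0.000582) and by 1.02 on average (adjusted p = 0.000128), and its value in uninduced cells was 0.66 (adjusted p = 0.110). After centring the value in uninduced cells was 1.02 and passed, and after cyclic loess it was 2.80 there, 2.78 in induced cells and 2.79 on average. RN7SK, a polymerase III RNA of the nucleus, changed by -0.71 on average (adjusted p = 0.0107), which did not pass without uninduced Xrn1 replicate 1 (-0.58) and which cyclic loess turned to 1.70. These 2 were the only measured members of a list of small RNAs with uncapped or triphosphate ends, too few for a list test.

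Among genes with a mean above 5, 68 with a symbol rose on average after Xrn1, and for 25 of them the untreated and Xrn1 values did not overlap in either induction state. The set mixes genes that many cells express with genes of other tissues, such as KRTAP5-3 of hair (1.08), PRTN3 of neutrophils (0.99) and the olfactory receptor OR10AC1 (0.86), so a mean above 5 measures signal and does not show that a gene is expressed. It also holds CALM3, a calmodulin gene (1.5), SAC3D1 (1.14), NDUFA1, a small subunit of complex I (1.02), and GUK1, a guanylate kinase (0.85). After cyclic loess the last 4 changed by 2.37, 2.06, 1.97 and 1.68.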
